A study of Mus musculus with 4 samples.

How the data were processed

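The data are 4 gene count tables, 1 per library, 2 labelled floxed control and 2 labelled conditional knockout. Per the labels' protocols, cortex was dissociated at embryonic day 17, RNA was poly(A)-selected, and libraries that mark the strand by dUTP were sequenced as paired reads. Per the submitters' processing notes, the tools were HISAT2 2.2.1, HTSeq 0.12.4 and DESeq2 1.26.0 with the mm10 build. The strand setting used in counting and the gene annotation are not given in the sources used here, so reads of overlapping or antisense genes, such as Xist and its antisense partner, cannot be told apart with certainty. The deposited values are raw counts per gene symbol, with no normalization, since they are whole numbers with different totals per library. Each table ends in 5 summary lines of reads not assigned to a gene. Those lines held 25.2% of all entries in control replicates 1 and 2, and 26.1% and 25.8% in knockout replicates 1 and 2, and were left out of library sizes and tests.

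Groups and replicate numbers were taken from the sample titles. Gene totals of 25936794 to 28263272 counts mean that a floor of 3 counts stands for 0.106 to 0.116 counts-per-million (CPM). For genes at 0 in a group a fold was computed against 3 counts per library and is a lower bound. Such floors cover counting error only, and the reads carry no molecular identifiers. The interval of the Prrc2b ratio was built from the standard error of the quasi-likelihood fit, so it includes the spread between these libraries. Before averaging, pairs of libraries were compared by a chi-square of their counts per gene over genes with at least 20 counts.

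Genotypes were compared with edgeR 4.0.16 in R 4.3.3: low-count genes were removed by filterByExpr, libraries were scaled by the trimmed mean of M values, and a quasi-likelihood F test was run with Benjamini-Hochberg adjustment over 15012 genes at a threshold of 0.05. The newer quasi-likelihood fit (legacy turned off) was the main test, and the legacy fit, which this version of the package runs unless told otherwise, was an alternative. The common biological coefficient of variation was 0.0242 and the prior degrees of freedom 34.3. Standard errors of log2 fold changes were the absolute fold change over the square root of F. Because 2 against 2 libraries allow no two-sided exact permutation p under 0.333, no permutation test was used for single genes.

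Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 29 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing it with other genes, were run beside it. Of the 31 lists, that of mitochondrially encoded genes had 0 tested members and that of erythroid genes 1, so neither was tested. The sex-linked genes were used to compare the sex of the libraries. Chromosome positions, GC content and lengths came from GENCODE release M21 on GRCm38, the same assembly as mm10, in which 24045 symbols (98.5%) were found.

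The lists, tests and alternatives were fixed before the data were examined. The rule for genes named was also fixed then. It takes Prrc2b, Prrc2a, Prrc2c, Nes, Xist and the Y-linked genes, and up to 4 tested members of each list with the smallest p, a few of which are not reported here. It adds the 10 largest rises and falls and the 5 smallest p in each direction among genes past the threshold. These last had a mean log2 CPM of at least 1, groups that do not overlap and no predicted-gene name. Families with close paralogs or many pseudogenes, such as ribosomal protein, Serpina3, Gbp, Oas-like and MHC class I genes, and X and Y homologs, are uncertain where the counting could have split their reads.

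The steps were tested on simulated counts for 14896 genes with the means and library sizes of this comparison. Genes were drawn independently with the same dispersion for all (coefficient of variation 0.0242), and changed genes were picked above a minimum expected count. Differences in dispersion between genes, correlation between genes and variation between embryos or pools were left out. The rates that follow therefore need not hold for the real libraries or for low-count genes. Of 50 genes changed at each size, 64% were recovered at 1.2-fold, 88% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 13 of 14696 unchanged genes were called. In a simulation with 1 of 29 lists raised by 1.2-fold, camera with the preset correlation called that list and 1 other that had not been raised. Alternatives covered other scalings (DESeq2-style size factors, upper quartile, total count), no low-count filter and one of 1 CPM in 2 libraries with 50 counts in all. They also covered DESeq2 1.42.0, limma voom, robust moderation, other thresholds, a replicate block, correction for GC content and length, removal of dominant gene classes, and omission of each library in turn. Tests against a 1.5-fold change, removal of X and Y genes, and list tests after GC and length correction were added after the data had been seen. So was the reading of Prrc2b in the test against a 1.2-fold change.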

Results

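Poly(A) RNA was sequenced from neural stem cells of the C57BL/6J mouse cerebral cortex, isolated at embryonic day 17 and kept for 1 day in medium containing basic FGF and EGF, the mitogens that keep these progenitors dividing. The 4 libraries form 2 groups of 2. Cells labelled floxed control carried Prrc2b alleles flanked by loxP sites and no Cre, and cells labelled conditional knockout carried the same alleles together with Nestin-Cre, a recombinase driven by regulatory sequence of the progenitor gene Nes. The comparison asks which transcripts differ in these progenitors when deletion of Prrc2b, a member of the proline-rich coiled-coil protein family, is induced. Counts assigned to genes came to 26491919 and 28263272 in control replicates 1 and 2, and to 28205590 and 25936794 in replicates 1 and 2 of the libraries labelled knockout. Between 17881 and 17948 genes had at least 1 count in a library, and 19264 in any. Libraries of the same group lay close together. The chi-square of their counts per gene was 1.96 for the controls and 2.2 for the libraries labelled knockout, above the value of 1 given by sampling alone, against 20.4 to 21.2 for pairs from different groups. Nothing in the labels says that the replicates came from separate embryos or cultures, so p-values measure only the spread between these libraries, which may be technical. In what follows, levels are counts-per-million (CPM) as mean ± SD over n = 2 libraries, and log2 fold changes are the libraries labelled knockout over control, ± SE.

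Prrc2b transcript was found at nearly the same level in both groups, at 590 ± 4.19 CPM in control and 575 ± 1.43 CPM in the libraries labelled knockout. The log2 fold change was -0.04 ± 0.02 (edgeR quasi-likelihood test, adjusted p = 0.134), and the 95% interval of the ratio ran from 0.940 to 1.00. The gene lies on the plus strand of chromosome 2 from 32151082 to 32234537 (mm10) and has 32 exons in a coding transcript of 10671 bp. Which exon the loxP sites flank is not given in the sources used here, and reads from the remaining exons would still be counted, so this gene total does not check the genotype label. After correction for GC content and length the value was -0.07 (adjusted p = 0.0069, the lowest of 18 alternatives). One of the 18 tested against a 1.2-fold change, and Prrc2b did not pass there. Among the rest, which tested for any difference, the highest adjusted p was 0.599, with upper quartile scaling. The paralogs gave -0.01 ± 0.02 for Prrc2a (adjusted p = 0.835), a value that changed sign to 0.02 with upper quartile scaling, and -0.09 ± 0.02 for Prrc2c (adjusted p = 0.0073). The Prrc2c call was lost with upper quartile scaling, with DESeq2, without control replicate 1 and without knockout replicate 2, with adjusted p from 0.00045 to 0.123 over 17 alternatives. Nes, whose regulatory sequence drives Cre and which encodes the progenitor intermediate filament nestin, was lower at 541 ± 0.23 against 628 ± 2.30 CPM (-0.22 ± 0.02, adjusted p = 1.6e-10).

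Y-linked transcripts separated the groups completely. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 24.0 ± 0.555, 21.4 ± 1.16, 13.7 ± 0.267 and 6.79 ± 0.00089 CPM in control and had 0 counts in both libraries labelled knockout. Against the 0.116 CPM that a floor of 3 counts per library represents, they were at least 207-fold, 185-fold, 119-fold and 58.7-fold lower. Xist, the RNA that coats the inactive X chromosome of female cells, was abundant in both groups, at 1639 ± 40.5 CPM in control and 2169 ± 64.2 CPM in the libraries labelled knockout (0.40 ± 0.02, adjusted p = 1.9e-18). Control libraries thus held Y-linked transcripts beside 75.6% of the Xist level of the other group. Genotype, presence of Cre and the sex of the embryos cannot be separated in any value that follows. Of 534 X-linked genes tested, 167 differed (31.3%; 94 higher and 73 lower), and of 14446 autosomal genes 4796 differed (33.2%).

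**Figure D1:**
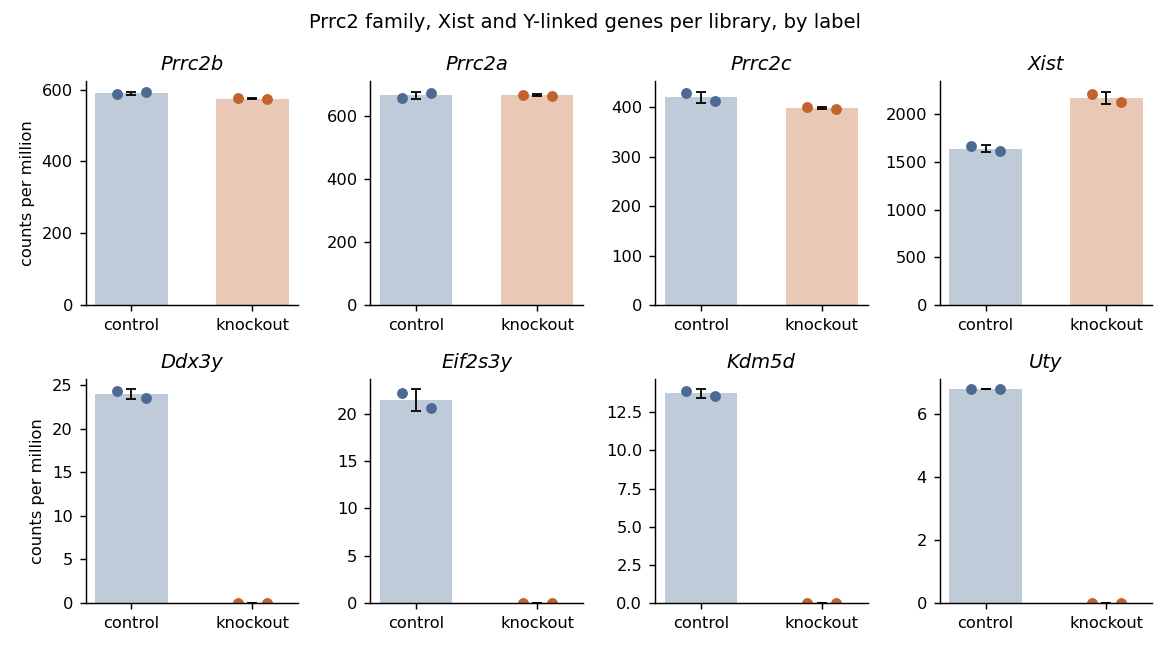
CPM (vertical axes, from 0) of Prrc2b, Prrc2a, Prrc2c, Xist and 4 Y-linked genes; bars are means, error bars SD, and points the 2 libraries of each label. Prrc2b stands at 590 and 575 CPM, and the Y-linked genes are at 0 in both libraries labelled knockout.

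Across the transcriptome, 2263 genes were higher and 2711 lower in the libraries labelled knockout among 15012 tested (adjusted p under 0.05), or 33.1% of the genes. Most of these differences were small. Of the 4974 genes, 4111 (82.6%) differed by less than 1.5-fold and the median absolute log2 fold change was 0.24, whereas 131 were at least 2-fold higher and 312 at least 2-fold lower. The libraries of the groups did not overlap for 9779 genes (65.1%), against 33.3% by chance with 2 against 2. DESeq2 called fewer genes, 1055 higher and 1642 lower. Upper quartile scaling gave 2939 higher and 2288 lower, so the balance between rises and falls depends on the scaling.

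**Figure D2:**
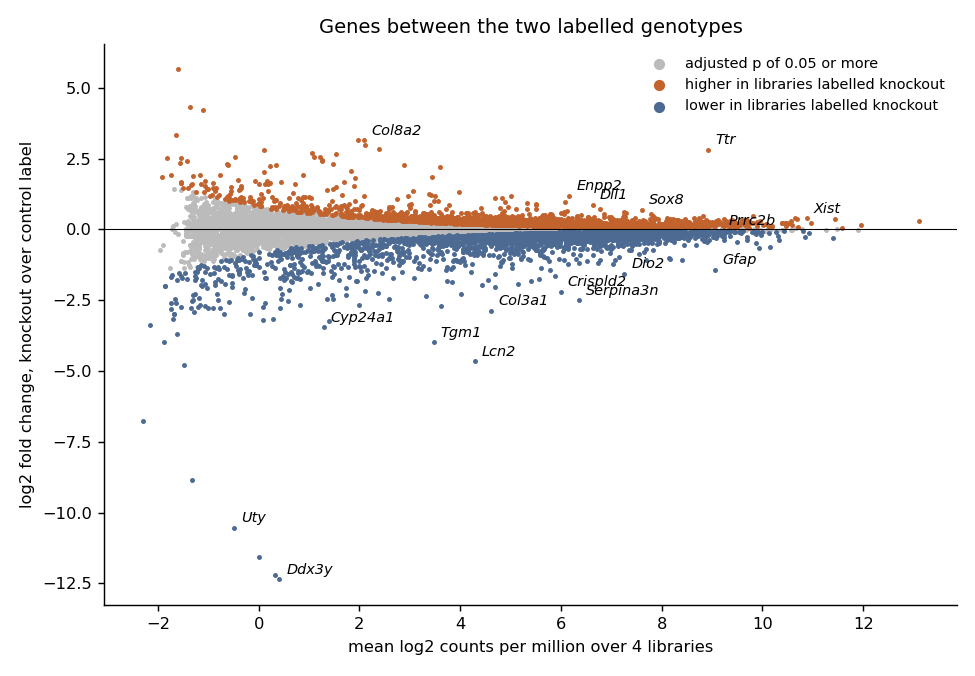
Log2 fold change, libraries labelled knockout over control (vertical axis), against the mean log2 CPM of all 4 libraries (horizontal axis); each point is 1 of 15012 genes, orange for the 2263 higher, blue for the 2711 lower and grey for the rest. Ttr (2.81) and Lcn2 (-4.66) stand far from the rest, and the fitted values of the Y-linked genes at the bottom are not bounds, since these genes had 0 counts in 1 group.

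The most abundant of the strongly raised transcripts was Ttr, the thyroid hormone carrier that choroid plexus epithelium secretes, which rose from 182 ± 5.15 to 1283 ± 13.3 CPM (log2 fold change 2.81 ± 0.02, adjusted p = 8.2e-44; chromosome 18, 20665280 to 20674321). The 10 largest rises ran from 2.46 to 3.15. They included the short-chain collagen gene Col8a2 (1.40 ± 0.322 to 12.4 ± 1.43 CPM) and the small leucine-rich proteoglycan gene Fmod (1.27 ± 0.252 to 11.5 ± 0.523 CPM). The folate receptor gene Folr1 rose from 1.49 ± 0.19 to 12 ± 1.09 CPM and the secreted BMP antagonist gene Sostdc1 from 1.91 ± 0.197 to 13.8 ± 0.386 CPM. The bicarbonate cotransporter gene Slc4a5 (2.69 ± 0.22), Tmem72 (2.67 ± 0.19) and the multiciliated cell regulator Gmnc (2.56 ± 0.22) were also among them. The epithelial keratin gene Krt8 (2.55 ± 0.21) and the potassium channel subunit gene Kcne2 (2.46 ± 0.20) completed the set. Control levels of these 5 genes were about 1 CPM or less. By smallest p, Ttr was followed by Enpp2, which encodes the secreted lysophospholipase autotaxin (47.3 ± 0.433 to 108 ± 1.29 CPM, 1.18 ± 0.04). Then came a further collagen VIII chain gene Col8a1 (2.19 ± 0.09), the glial transcription factor gene Sox8 (0.69 ± 0.03) and the Notch ligand gene Dll1 (0.87 ± 0.04). In a list of choroid plexus genes drawn up after these rises had been seen, 13 of 23 tested genes rose and 2 fell.

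The deepest autosomal fall among genes of at least 1 mean log2 CPM was that of Lcn2, the iron-siderophore carrier lipocalin and an acute-phase gene, from 96.9 ± 1.35 to 3.87 ± 0.412 CPM (-4.66 ± 0.07, adjusted p = 1.4e-35). Lcn2 lies on chromosome 2 from 32384633 to 32388252. Next came the transglutaminase gene Tgm1 (43.7 ± 1.02 to 2.75 ± 0.177 CPM) and the vitamin D catabolic gene Cyp24a1 (7.72 ± 0.034 to 0.698 ± 0.115 CPM). The metalloreductase gene Steap4 fell from 7.67 ± 0.144 to 0.814 ± 0.0482 CPM and the fibrillar collagen gene Col3a1 from 65.7 ± 2.05 to 9.01 ± 0.612 CPM. The transcription factor gene Sox7 (-2.70 ± 0.09), the protease inhibitor gene Serpina3n (-2.49 ± 0.04) and the interferon-inducible genes Oasl2 (-2.69 ± 0.16), Gbp6 (-2.47 ± 0.19) and Ifi27 (-2.46 ± 0.13) were the remainder of the 10. Serpina3n, Oasl2 and Gbp6 belong to families of close paralogs, among which reads could have been split. By smallest p, Lcn2 and Serpina3n were followed by Gfap, the astrocyte intermediate filament gene (867 ± 13.9 to 326 ± 3.54 CPM, -1.42 ± 0.02). Crispld2 fell from 136 ± 0.78 to 29.7 ± 0.0111 CPM. Dio2, whose enzyme converts thyroid hormone to its active form, fell from 263 ± 9.74 to 89.3 ± 1.3 CPM.

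**Figure D3:**
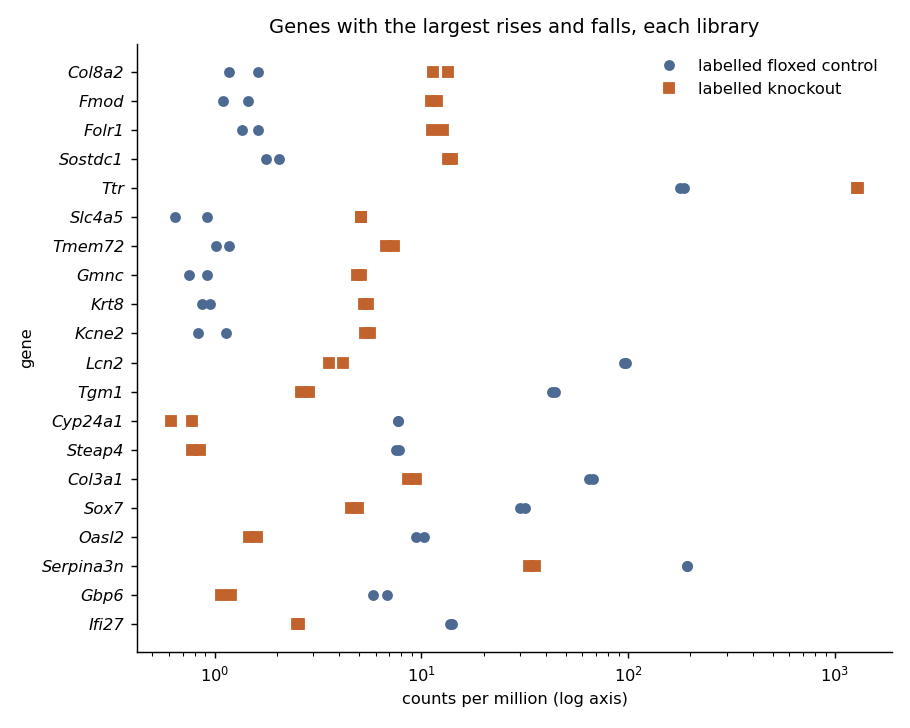
CPM on a log axis (horizontal) for the 10 genes with the largest rises and the 10 with the largest falls (vertical axis); circles are the 2 control libraries and squares the 2 libraries labelled knockout. Genes were chosen among those whose groups do not overlap; Ttr stands at 182 against 1283 CPM.

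Gene lists fixed before the data were examined were then compared with all other genes. Of 29 lists tested with camera at a preset correlation of 0.01, 6 were higher and 10 lower in the libraries labelled knockout at adjusted p under 0.05. None held in camera with a correlation estimated from the 4 libraries, where the lowest adjusted p was 0.283 and 2 lists, interferon-stimulated genes and FGF and EGF receptor feedback genes, had an unadjusted p under 0.05. For 15 of the 16 lists camera with an estimated correlation gave the highest adjusted p over all alternatives. The camera calls thus rest on the preset form of the test. The size of the correlation does not account for every loss. It was estimated above 0.01 for some lists, such as immediate early genes (0.306), and below for others, such as interferon-stimulated genes (-0.037). With 4 libraries the estimated form has few residual degrees of freedom, so a miss there is weak evidence against a list. By fry 24 lists passed. Those that passed by fry as lower but not by camera were GABAergic interneuron, endothelial, heat shock, glycolysis and hypoxia, and Sonic hedgehog genes. Those that did so as higher were G2 and M phase, integrated stress response and translation initiation genes.

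Among the neural lists, those of intermediate progenitors, the oligodendrocyte lineage and cortical neurons were higher. Of 15 tested genes of intermediate progenitors and proneural factors, 11 rose and 1 fell, also when adjusted over the list alone. The median log2 fold change was 0.24 (camera adjusted p = 0.00083, and adjusted p = 0.283 with an estimated correlation). Dll1 rose from 73.3 ± 2.36 to 134 ± 2.79 CPM, the Notch ligand gene Dll3 from 26.9 ± 0.217 to 44.5 ± 1.57 CPM, Rhbdl3 by 0.44 ± 0.06 and the antiproliferative gene Btg2 by 0.28 ± 0.03. Oligodendrocyte lineage genes were higher as well, with 9 of 19 risen and 2 fallen (10 and 2 adjusted over the list alone). The median was 0.26 (adjusted p = 0.00052, and adjusted p = 0.283 with an estimated correlation). Examples are the receptor gene Gpr17 (0.72 ± 0.05), Sox8 (0.69 ± 0.03), the NG2 proteoglycan gene Cspg4 (0.49 ± 0.04) and Bcas1 (0.49 ± 0.05). Of 24 cortical and pan-neuronal genes 10 rose and 2 fell, also adjusted over the list alone. The median was 0.08 (adjusted p = 0.0313, and adjusted p = 0.325 with an estimated correlation). The microtubule regulator gene Stmn2 rose from 371 ± 3.05 to 490 ± 13.8 CPM, the cortical neuron transcription factor gene Neurod6 by 0.44 ± 0.03, the neuronal tubulin gene Tubb3 by 0.25 ± 0.02 and the growth cone gene Gap43 by 0.21 ± 0.03. That neuronal list missed the threshold without control replicate 2 (adjusted p = 0.0831) or knockout replicate 1 (adjusted p = 0.0686), and the 14 alternatives ranged from 0.0049 to 0.325.

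Genes of radial glia and of astrocytes were lower. Microglial, mural cell and fibroblast markers fell in the same libraries, as given below. Of 22 neural stem and radial glial genes 10 fell and 4 rose, also adjusted over the list alone. The median was -0.07 (adjusted p = 0.0271, and adjusted p = 0.302 with an estimated correlation). The intermediate filament gene Vim fell from 2994 ± 0.901 to 2421 ± 5.68 CPM, the glutamate transporter gene Slc1a3 from 1459 ± 25.5 to 1144 ± 3.46 CPM. The matrix gene Tnc fell from 1217 ± 6.55 to 781 ± 4.53 CPM, while the Notch target Hes5 rose from 33.4 ± 2.06 to 62.3 ± 6.75 CPM. Of 19 astrocyte genes 11 fell and 4 rose, also adjusted over the list alone. The median was -0.15 (adjusted p = 0.0271, and adjusted p = 0.302 with an estimated correlation). Gfap fell most, the water channel gene Aqp4 fell by 0.62 ± 0.03 and the matricellular gene Sparcl1 by 0.44 ± 0.02 on the log2 scale, while the receptor gene Fgfr3 rose by 0.59 ± 0.03. The radial glial list missed the threshold when control replicate 2 (adjusted p = 0.0646), knockout replicate 1 (0.0686) or knockout replicate 2 (0.0708) was left out, and with the replicate block (0.0506). The astrocyte list missed it without control replicate 2 (0.101) or knockout replicate 1 (0.0503), and both lists ranged from 0.0062 to 0.302 over 14 alternatives. GABAergic interneuron genes did not pass as a list (adjusted p = 0.0525), although 10 of 17 fell and 3 rose, also adjusted over the list alone. The GABA-synthesizing enzyme gene Gad2 (-0.38 ± 0.06) and the transcription factor gene Sp8 (-0.45 ± 0.10) were lower and the neuropeptide gene Sst higher (0.29 ± 0.04). This interneuron list passed in 7 of 14 alternatives: upper quartile or total count scaling, no low-count filter, the replicate block, GC and length correction, fry, and without knockout replicate 2. Its adjusted p ranged from 0.0214 to 0.316. Synapse and ion channel genes moved both ways, with 7 risen and 6 fallen of 27 (7 and 7 adjusted over the list alone; adjusted p = 0.922). Their median (-0.0051) and mean (-0.013) were negative where the test direction was up, and the median was positive in 4 of 14 alternatives, upper quartile scaling among them. The synaptotagmin gene Syt4 was higher (0.33 ± 0.03), whereas the GABA receptor gene Gabra2 (-0.86 ± 0.08) and the NMDA receptor gene Grin2b (-0.61 ± 0.06) were lower.

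Markers of microglia and of mural cells and fibroblasts were lower in the libraries labelled knockout. Of 11 tested microglia and macrophage genes 7 fell and 4 did not pass, also adjusted over the list alone. The median was -1.39 (adjusted p = 0.00095, and adjusted p = 0.316 with an estimated correlation). The 7 were scarce in control, at 0.856 to 1.55 CPM. The complement gene C1qb fell from 0.98 ± 0.265 to 0.146 ± 0.0436 CPM, C1qc from 0.951 ± 0.0435 to 0.153 ± 0.166 CPM and the lysosomal protease gene Ctss from 1.42 ± 0.193 to 0.456 ± 0.208 CPM. The list missed the threshold with the stricter low-count filter (adjusted p = 0.0566, in a range of 1.6e-05 to 0.316 over 14 alternatives). Mural cell, fibroblast and meningeal genes fell for 11 of 17 and rose for 2, also adjusted over the list alone. The median was -0.87 (adjusted p = 0.00052, and adjusted p = 0.283 with an estimated correlation). The fibrillar collagen genes Col1a1 (52.0 ± 1.14 to 12.7 ± 1.2 CPM) and Col1a2 (37.6 ± 0.0885 to 19.6 ± 1.45 CPM) fell with Col3a1, while the proteoglycan gene Ogn rose from 1.70 ± 0.103 to 7.18 ± 0.228 CPM. Endothelial genes did not pass as a list in camera (adjusted p = 0.908), with 3 of 13 fallen and 2 risen, also adjusted over the list alone. Their median (0.11) and mean (0.03) were positive and the test direction was down. By fry the list passed as lower (adjusted p = 0.0480). The glucose transporter gene Slc2a1 (168 ± 0.337 to 94.2 ± 1.72 CPM) and the VEGF receptor gene Flt1 (11.9 ± 0.953 to 4.23 ± 0.12 CPM) fell. The cadherin gene Cdh5 fell from 2.40 ± 0.239 to 1.02 ± 0.243 CPM, and Slco1a4 rose from 0.258 ± 0.115 to 1.31 ± 0.60 CPM. Of the 12 erythroid genes Alas2 was the single member counted often enough to test, at 0.445 ± 0.279 and 0.401 ± 0.185 CPM. Its log2 fold change was -0.12 ± 0.49 (adjusted p = 0.888), which turned to 0.70 without control replicate 1 and to 0.27 without knockout replicate 2.

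**Figure D4:**
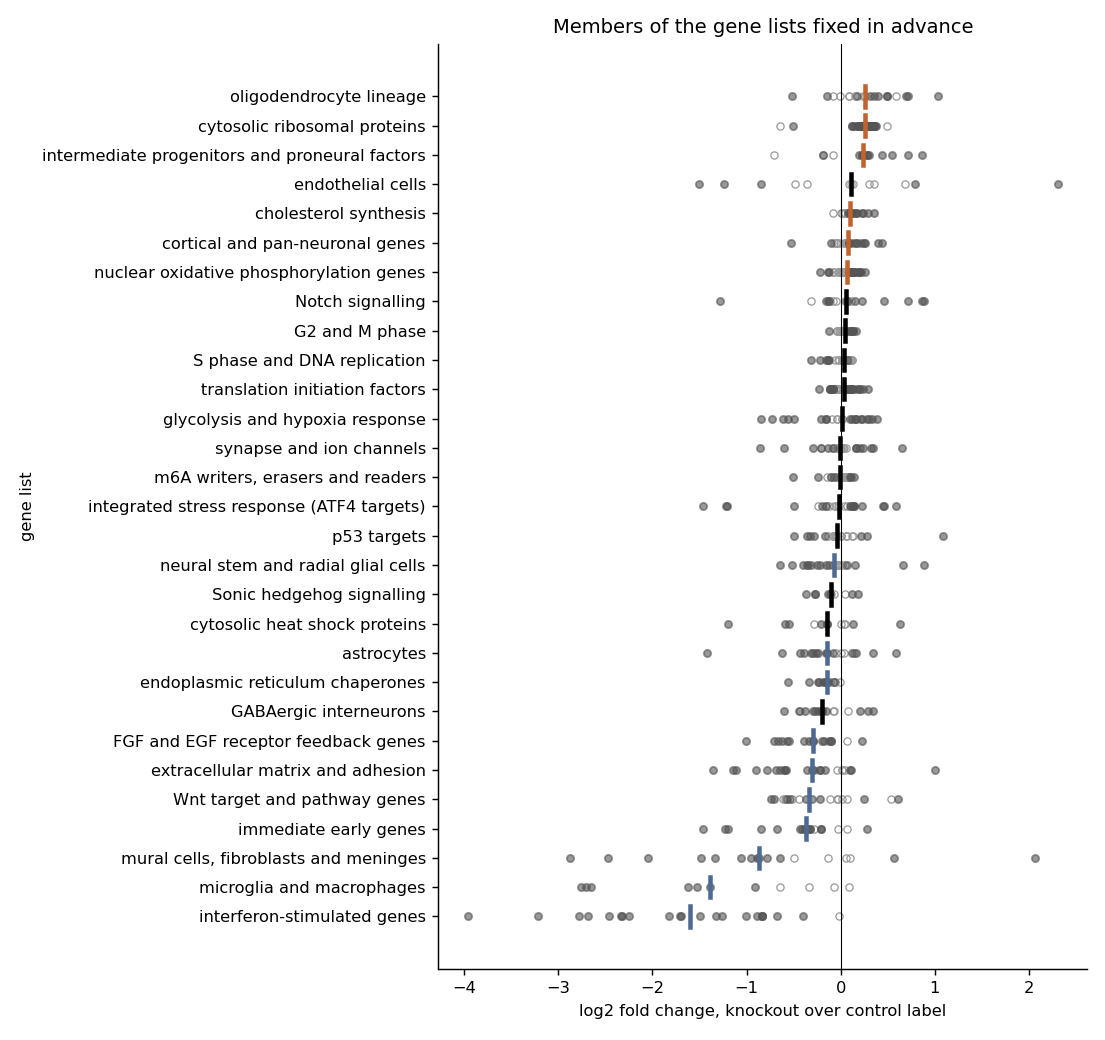
Log2 fold changes, libraries labelled knockout over control (horizontal axis), of the members of 29 gene lists (vertical axis); filled points passed adjusted p under 0.05 and open points did not. Thick bars are list medians, orange for the 6 lists higher and blue for the 10 lower with the preset correlation and black for the rest; interferon-stimulated genes have the lowest median at -1.60.

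Interferon-stimulated genes showed the most uniform decrease of the signalling lists fixed before the data were examined. Of 22 tested 21 fell and 1 did not pass, also adjusted over the list alone. The median was -1.60 (adjusted p = 1.0e-13, and adjusted p = 0.283 with an estimated correlation). Examples are Ifi27 (13.9 ± 0.19 to 2.53 ± 0.0329 CPM), Oasl2 (9.86 ± 0.684 to 1.53 ± 0.0922 CPM) and the antiviral tetherin gene Bst2 (26.3 ± 1.12 to 11.0 ± 0.0246 CPM). Genes of the FGF and EGF receptor feedback list fell for 15 of 17 and rose for 1, also adjusted over the list alone. Besides feedback genes the list holds the receptor genes Egfr, Fgfr1 and Fgfr2, and Ccnd1. The median was -0.30 (adjusted p = 2.4e-05, and adjusted p = 0.283 with an estimated correlation). The cyclin gene Ccnd1 fell from 1409 ± 3.73 to 920 ± 5.31 CPM. The ERK phosphatase genes Dusp4 and Dusp6 fell by 1.00 ± 0.05 and 0.70 ± 0.04, and the receptor signalling inhibitor gene Spry4 by 0.55 ± 0.04 on the log2 scale. Immediate early genes fell for 13 of 18 and rose for 1 (14 and 1 adjusted over the list alone). The median was -0.36 (adjusted p = 5.1e-06, and adjusted p = 0.316 with an estimated correlation). Ier3 dropped from 161 ± 9.04 to 70.3 ± 2.10 CPM. The AP-1 transcription factor genes Junb and Jun fell from 108 ± 3.22 to 46.5 ± 0.563 CPM and from 329 ± 9.45 to 254 ± 0.00836 CPM, and Arc was at -0.84 ± 0.07. Microglial and fibroblast markers fell alongside these lists, as given above.

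Extracellular matrix and adhesion genes fell for 16 of 23 and rose for 3 (16 and 4 adjusted over the list alone). The median was -0.31 (adjusted p = 0.00011, and adjusted p = 0.283 with an estimated correlation). Tnc was joined by the collagen genes Col6a1 (41.4 ± 0.861 to 18.7 ± 0.613 CPM), Col4a1 (134 ± 1.54 to 89.9 ± 5.09 CPM) and Col5a1 (81.6 ± 2.52 to 53.9 ± 0.12 CPM). Mural cell and fibroblast markers fell in the same libraries, as given above. Wnt target and pathway genes fell for 7 of 20 and rose for 2, also adjusted over the list alone. The median was -0.33 (adjusted p = 0.0144, and adjusted p = 0.316 with an estimated correlation). The secreted Dickkopf-family gene Dkk3 (-0.71 ± 0.03), the receptor gene Fzd1 (-0.74 ± 0.05) and the ligand gene Wnt7a (-0.36 ± 0.04) were lower, and the Wnt feedback inhibitor gene Nkd1 higher (0.61 ± 0.07). Notch pathway genes did not pass as a list (adjusted p = 0.368), with 7 risen and 4 fallen of 21 (7 and 5 adjusted over the list alone). The ligand genes Dll1 and Dll3 rose with the target Hes5 (0.89 ± 0.06) whereas a further ligand gene, Jag1, fell from 43.2 ± 1.82 to 17.8 ± 0.27 CPM. Sonic hedgehog genes did not pass either (adjusted p = 0.210), with 5 fallen and 2 risen of 10, also adjusted over the list alone. The co-receptor genes Gas1 (-0.27 ± 0.04), Boc (-0.37 ± 0.06) and Cdon (-0.13 ± 0.03) and the transcription factor gene Gli3 (-0.27 ± 0.05) were lower.

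Cytosolic ribosomal protein genes rose with few exceptions, by small amounts. Of 78 tested 74 rose and 1 fell, also adjusted over the list alone. The median was 0.25 (adjusted p = 2.0e-19, and adjusted p = 0.283 with an estimated correlation). Rps26 (532 ± 2.51 to 682 ± 34.2 CPM), Fau (311 ± 12 to 401 ± 9.69 CPM) and Rpl13a (600.1 ± 29.1 to 756 ± 14.3 CPM) rose, and Rpl17 fell from 214 ± 0.11 to 152 ± 14.4 CPM. Many of these genes have processed pseudogenes with which reads could be shared. Correction for GC content and length lowered the median to 0.14 (adjusted p = 2.0e-12, in a range of 1.6e-20 to 0.283 over 13 alternatives). Translation initiation factors were mixed, with 13 risen and 7 fallen of 31 (14 and 9 adjusted over the list alone; adjusted p = 0.282). Eif1 (0.29 ± 0.03), Eif3h (0.21 ± 0.03) and Eif3k (0.24 ± 0.03) were higher and the scaffold gene Eif4g1 lower, at 511 ± 4.13 against 595 ± 1.79 CPM. Writers, erasers and readers of the RNA mark N6-methyladenosine mostly stayed under the threshold, with 3 risen and 4 fallen of 23, also adjusted over the list alone (adjusted p = 0.908). Igf2bp2 (-0.51 ± 0.04) and Zc3h13 (-0.24 ± 0.04) were lower and Hnrnpc (0.14 ± 0.03) and Rbmx (0.10 ± 0.03) higher. The Rbmx call was lost with DESeq2 (adjusted p = 0.0952), without control replicate 1 (0.0872) and without knockout replicate 1 (0.0906), in a range from 0.001 over 17 alternatives.

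Of the stress lists, endoplasmic reticulum chaperones passed as lower. Of 15 tested 9 fell and 6 did not pass, also adjusted over the list alone. The median was -0.15 (adjusted p = 0.00052, and adjusted p = 0.283 with an estimated correlation). The BiP gene Hspa5 fell from 456 ± 4.20 to 392 ± 1.56 CPM, Calr from 557 ± 11.3 to 492 ± 14.7 CPM, Hyou1 by 0.24 ± 0.03 and Creld2 by 0.33 ± 0.06 on the log2 scale. Heat shock genes fell for 6 of 12 and rose for 2, also adjusted over the list alone, without passing as a list (adjusted p = 0.148). The co-chaperone gene Bag3 was at -0.59 ± 0.05, Hsph1 at -0.21 ± 0.03, Hspd1 at -0.14 ± 0.02 and Hspa4 at -0.15 ± 0.03. Integrated stress response genes moved both ways, with 9 risen and 6 fallen of 24 (10 and 6 adjusted over the list alone; adjusted p = 0.908). Their median (-0.02) and mean (-0.12) were negative where the test direction was up, and the median was positive with upper quartile scaling and without control replicate 1. The asparagine synthetase gene Asns (0.46 ± 0.04) and the aminotransferase gene Gpt2 (0.45 ± 0.03) were higher and the cystine transporter gene Slc7a11 lower (-1.21 ± 0.06). Cebpb also fell, from 29.0 ± 10.1 to 12.5 ± 2.57 CPM, but its controls were far apart. That call was lost with robust empirical Bayes moderation (adjusted p = 0.205, the highest of 17 alternatives, the lowest being 1.1e-71). Targets of p53 did not pass as a list (adjusted p = 0.513), with 3 risen and 5 fallen of 22, also adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a (-0.29 ± 0.03) and Phlda3 (-0.36 ± 0.04) were lower and Perp (1.08 ± 0.12) and Btg2 higher.

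Cholesterol synthesis genes rose for 13 of 21 and 8 did not pass, also adjusted over the list alone. The median was 0.10 (adjusted p = 0.00052, and adjusted p = 0.298 with an estimated correlation). The synthase genes Hmgcs1 (825 ± 13.3 to 978 ± 0.49 CPM) and Fdps (113 ± 4.65 to 146 ± 1.46 CPM), the kinase gene Pmvk (0.29 ± 0.05) and the squalene synthase gene Fdft1 (0.17 ± 0.03) were higher. Nuclear oxidative phosphorylation genes rose for 15 of 32 and fell for 3 (15 and 5 adjusted over the list alone). The median was 0.07 (adjusted p = 0.0363, and adjusted p = 0.316 with an estimated correlation). Cox7c (0.21 ± 0.03), Atp5o (0.20 ± 0.03) and Atp5c1 (0.13 ± 0.03) were higher and Uqcrc1 lower (-0.22 ± 0.03). Correction for GC content and length turned the median of this list to -0.03 (adjusted p = 0.366) and ended the calls of Cox7c and Atp5o. This list missed the threshold when any 1 library was left out (adjusted p from 0.0642 to 0.0881) and with the replicate block (0.0552), in a range of 0.0199 to 0.366 over 14 alternatives. Glycolysis and hypoxia genes split, with 10 risen and 8 fallen of 24 (10 and 9 adjusted over the list alone; adjusted p = 0.908), a positive median (0.01), a negative mean (-0.06) and an upward test direction. The glycolytic kinase gene Pgk1 rose from 1401 ± 24.7 to 1847 ± 1.76 CPM, while Slc2a1, the glycolytic regulator gene Pfkfb3 (-0.73 ± 0.03) and Ndrg1 (-0.61 ± 0.03) fell.

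Neither of the cell cycle lists passed. S phase and DNA replication genes fell for 5 of 24 and rose for 1, also adjusted over the list alone (adjusted p = 0.908; median 0.04, mean -0.01, test direction up). Rrm2 (-0.13 ± 0.03), Mcm3 (-0.15 ± 0.03), Tyms (-0.31 ± 0.07) and Mcm2 (-0.12 ± 0.04) were lower. G2 and M phase genes rose for 7 of 24 and fell for 1, also adjusted over the list alone, without passing as a list (adjusted p = 0.106), although it passed with upper quartile scaling (0.0491) and by fry (0.0380). The kinetochore gene Cenpf (0.14 ± 0.03), Top2a (0.09 ± 0.02), Ube2c (0.13 ± 0.04) and Cdc20 (0.12 ± 0.03) were higher. Mcm2 lost its call with DESeq2 (adjusted p = 0.0975) and without knockout replicate 1 (0.0585), and Ube2c with DESeq2 (0.0744). For Cdc20 the call was lost with DESeq2 (0.0878), without control replicate 1 (0.178) and without knockout replicate 2 (0.0715), and over 17 alternatives the lowest adjusted p was 0.0035 for Mcm2, 0.00061 for Ube2c and 0.00061 for Cdc20.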

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

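Shares of reads that were assigned to no gene were not part of any comparison. All 5 summary lines were examined, and in 4 of them both libraries labelled knockout lay above both controls, which chance gives for 16.7% of lines in this direction. Reads outside annotated genes made up 13.9% against 13.5 ± 0.158% in control, ambiguous reads 2.09% against 2.05 ± 0.0205%, unaligned reads 1.04% against 0.987 ± 0.0635%, and reads with several alignments 5.16% against 4.87 ± 0.0125% (means, control ± SD, n = 2). The lines share a denominator and are not independent. No explanation was tested for these differences.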

How the results depend on the processing

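List tests after GC and length correction, the tests against a 1.5-fold change and the removal of X and Y genes were chosen after the data had been seen. So was the reading of Prrc2b against a 1.2-fold change. Of 140 named genes other than Prrc2b, 138 were called, and 129 kept direction and call in the alternatives run, 17 for each gene and 16 for 9 of the 140 that a filter or the removal of ribosomal protein genes took out once; the 11 that did not included Prrc2a, Prrc2c, Mcm2, Ube2c, Cdc20, Rbmx, Cebpb, Cox7c, Atp5o and Alas2. Counts of genes moved with the threshold: 1490 were higher and 2045 lower at adjusted p under 0.01, 131 higher and 312 lower at 2-fold or more, 279 and 760 when tested against 1.2-fold, and 74 and 296 when tested against 1.5-fold. DESeq2 called 1055 higher and 1642 lower, and all 2697 were among the 4974 genes of the main test. Most named genes were picked for a small p or a large change in these same data. That 129 of 140 held therefore does not describe the 4974 called genes. Without X and Y genes 2186 were higher and 2629 lower. Leaving out each library in turn gave 1738 to 1843 higher and 2249 to 2442 lower genes, 4 to 5 lists higher and 8 to 10 lower, and -0.05 to -0.04 for Prrc2b; the lone library is then assumed to vary like the other group. Prrc2b moved to -0.070 with GC and length correction (adjusted p = 0.0069) and to -0.071 with a replicate block and that correction (adjusted p = 0.0070); the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower in camera (2 at unadjusted p under 0.05), against 9 and 15 by fry. Signs turned for Prrc2a (0.019 with upper quartile scaling, and -0.025 to 0.0086 leaving out each library), for Alas2 (-0.70 to 0.70 leaving out each library) and for the oxidative phosphorylation list (-0.027 with GC and length correction); the cause was not tested. Of the lists that did not pass, 5 had a median that changed sign in at least 1 alternative: endothelial, integrated stress response, N6-methyladenosine, glycolysis and hypoxia, and synapse and ion channel genes. Of the 16 lists that passed, 11 kept their call in the alternatives run other than the set tests, 12 for each list and 11 for ribosomal protein genes. Deviations of same-numbered libraries had a correlation of -0.016 across 15012 genes, so no shared effect of the replicate number was seen. Whether same-numbered libraries were prepared together cannot be told from this value. The replicate block gave 2442 higher and 2881 lower genes, -0.04 for Prrc2b, and 5 lists higher and 10 lower. Low depth limits Alas2 and the microglial genes that fell, which stood at 0.445 to 1.55 CPM in control.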

Other observations

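Tests of one pool of cells, of embryo sex and of Prrc2b below were chosen after the results were seen. The choroid plexus, fibroblast, cytokine and MHC class I lists were drawn up after the first results and before their own values were looked at, and the X-escape list after the sex-linked genes had been seen.

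Genes of the NF-kappaB and cytokine response were lower without exception in the libraries labelled knockout. All 18 tested fell, also adjusted over the list alone, with a median log2 fold change of -1.01 (camera adjusted p = 1.1e-12, and adjusted p = 0.075 with an estimated correlation). The copper carrier gene Cp fell from 104 ± 1.77 to 33.5 ± 0.13 CPM (SD, n = 2) and the hyaluronan receptor gene Cd44 from 198 ± 7.59 to 102 ± 1.72 CPM. Timp1 fell from 44.5 ± 0.753 to 14.9 ± 0.988 CPM and the oncostatin M receptor gene Osmr from 21.5 ± 0.468 to 7.92 ± 0.469 CPM. The feedback inhibitor gene Socs3 fell from 43.8 ± 0.503 to 22.1 ± 0.736 CPM. Microglial markers (7 of 11, median -1.39) and mural cell and fibroblast markers (11 of 17, median -0.87) fell in the same libraries. MHC class I and antigen processing genes fell for 8 of 10 (9 adjusted over the list alone). The median was -0.62 (adjusted p = 2.8e-06, and adjusted p = 0.075 with an estimated correlation). B2m fell from 194 ± 1.74 to 92.4 ± 0.0965 CPM and the immunoproteasome gene Psmb8 from 9.07 ± 0.386 to 3.16 ± 0.00433 CPM. X-linked genes known to escape inactivation rose for 3 of 8, also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0396, and adjusted p = 0.167 with an estimated correlation). The 3 were Mid1 (0.57 ± 0.08), 5530601H04Rik (0.35 ± 0.09) and Eif2s3x (0.11 ± 0.03). The other 5 did not pass, among them Kdm6a (0.04 ± 0.04), Kdm5c (-0.003 ± 0.03) and Ddx3x (0.03 ± 0.02). Of all tested genes 33.1% differed.

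Choroid plexus epithelium genes rose for 13 of 23 and fell for 2 (14 and 3 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.00038, and adjusted p = 0.075 with an estimated correlation). The potassium channel gene Kcnj13 (2.03 ± 0.31), Kl (1.94 ± 0.42) and the roof plate transcription factor genes Msx1 (1.67 ± 0.28) and Lmx1a (1.64 ± 0.30) rose from under 1 CPM, and Igf2 rose from 23.3 ± 0.0314 to 40.3 ± 1.40 CPM. Otx2, which choroid plexus cells express, stood at 21.5 ± 0.285 and 21.8 ± 0.458 CPM, and the ciliary gene Foxj1 fell by 0.45 ± 0.06 on the log2 scale. The most abundant member, Igfbp2, was at 1598 ± 55.6 and 1658 ± 24.9 CPM (0.05 ± 0.02, adjusted p = 0.0944), and 16 of the 23 genes reached 1 CPM or more in control. Fibroblast genes fell for 10 of 17 and rose for 1 (12 and 1 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.00038, and adjusted p = 0.075 with an estimated correlation). Loxl1 fell from 52.3 ± 0.602 to 26.1 ± 0.32 CPM and Prrx1 from 102 ± 2.58 to 56.4 ± 1.83 CPM, while Fbln2 rose from 705 ± 4.55 to 834 ± 3.54 CPM.

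Lcn2, with the largest fall among the named autosomal genes, lies 150 kb from Prrc2b on chromosome 2. Of 46 other genes tested within 1 Mb of Prrc2b, Lcn2 among them, 17 differed (37.0%), 5 higher and 12 lower, with a median of -0.02. That share is near the 33.1% of all tested genes. Apart from Y-linked genes, Rbp3 and Crx, both known from photoreceptors and the pineal gland, were the 2 tested genes with 0 counts in both libraries labelled knockout. Chosen after their values were seen, they had 55 and 61 counts (Rbp3) and 14 and 13 counts (Crx) in control replicates 1 and 2, and were at least 18.3-fold and 4.27-fold lower against a floor of 3 counts per library.

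The first pattern weighed is the shift in genes of other cell types and of the cytokine response. A cytokine list whose values had not been looked at had a median of -1.01, below the -0.5 set beforehand, which extends the pattern to more genes. A lower response in general cannot be told apart from fewer microglia or fibroblasts, because their markers fell as well. The microglial markers were scarce in control (C1qb 0.98 CPM, Ctss 1.42 CPM) beside Cd44 at 198 CPM. Whether so scarce a cell type could account for falls of this size was not tested. More choroid plexus cells could not be told apart from other causes, because the median of the fresh list, 0.229, fell between the bounds of 0.2 and 0.5 set beforehand. That median is a poor guide, since the list mixes abundant genes, such as Igfbp2 at 1598 CPM in control, with scarce ones. Of members under 1 CPM in control, Kcnj13, Kl, Msx1, Lmx1a and Slc13a4 rose, while Prlr and Slco1a5 did not pass. Of the list's 23 tested genes 13 rose, Kcnj13 (2.03 ± 0.31) among them, and 2 fell. Another 8 did not pass, Otx2 (0.02 ± 0.07) among them. By design the list left out the genes first seen to rise, such as Ttr. Fewer fibroblasts likewise stayed open, with a median of -0.458 against bounds of -0.2 and -0.5. Genotype itself stays among the open explanations and was not tested apart from dissection, sex and culture.

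The second pattern is that many genes differed between groups while the libraries within a group lay close together. Whether both libraries of a group come from 1 pool of cells stays open. Y-linked genes gave 1784 and 1824 counts in the controls, shares that did not differ beyond counting error (two-sided exact binomial p = 0.206), and with 0 such counts the libraries labelled knockout allow no such test. The common biological coefficient of variation of 0.0242 also lay under the bound chosen for 1 pool after the results were seen. Both values are what 1 pool would give, but separate cultures that are alike could give them too, so neither decides. If both libraries of a group do come from 1 pool, the p-values describe 1 pool against another. The sex make-up of the embryos cannot be told apart from genotype, since X-linked genes differed no more often than autosomal genes (-1.93 percentage points) but X inactivation and autosomal effects of sex leave that share uninformative. Genotype remains open and untested.

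The third pattern is the level of Prrc2b. Loss of the whole transcript in most cells labelled knockout is argued against by the 95% interval of the ratio, whose lower bound was 0.940. Loss of a single exon could leave the count as it is by exon length alone, since 29 of 30 internal coding exons are each a smaller share of the transcript than the 6.03% fall that the interval allows. However, 23 of the 29 are not a whole number of codons long. Losing any of these would shift the reading frame or, for exon 2, the first coding exon, remove the start. Decay of the transcript could then lower the whole count, and which exon is deleted is not given in the sources used here. A culture in which little recombination took place would give the same gene count and was not tested apart from it.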
